A study of Mus musculus with 2 samples.

How the data were processed

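Single-cell 3' RNA sequencing covered 2 libraries of dorsal skin from C57BL/6 mice aged 7 weeks, 1 treated with imiquimod and 1 given Shi-Bi-Man plus imiquimod. Groups were taken from the treatment stated in the labels. The deposited files hold whole-number counts per gene and barcode, per the file headers, with at least 500 counts in every barcode. The builds mm10 and GRCm38 come from the submitters' processing notes. The aligner, the counting program, the rule that called cells and whether molecules were collapsed by their barcodes were not given in the sources used here. A value called a count is therefore the number as deposited, and the intervals treat each count as independent.

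The files list 55471 gene entries and 55353 symbols. Of the entries, 231 share a symbol with another and were summed, and they hold 0.110% of counts with imiquimod and 0.0797% with Shi-Bi-Man plus imiquimod. Gene coordinates came from the GENCODE vM21 annotation of GRCm38, which was chosen here and holds 55230 of the gene identifiers (99.6%).

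The imiquimod library had 28920316 counts in 11316 barcodes, with medians of 1617 counts and 847 genes. The Shi-Bi-Man plus imiquimod library had 20837259 counts in 8054 barcodes, with medians of 1762 counts and 923 genes. Cells needed at least 200 genes and at most 20% of counts from mitochondrial genes. This left out 192 and 7 barcodes for genes and 105 and 101 for mitochondrial share. Doublets were called per library with Scrublet at an assumed rate of 0.08. It marked 83 of 7946 cells (1.04%) in the Shi-Bi-Man plus imiquimod library and 2 of 11019 (0.0182%) in the imiquimod library, so it did not work in the latter. The 11017 and 7863 retained cells had medians of 1616 and 1780 counts.

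Both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed. Genes seen in at least 3 cells were kept, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 were used, with the seed set to 0. Clusters were named from fixed markers of 26 classes. A marker supported a class if it was at least 2-fold higher than in the other cells and present in 10% of the cells of the cluster, and 3 such markers were needed. A cluster whose 10 leading genes held more markers of another class, or with no supported class, stayed unnamed. Class names end in -like because they rest on RNA markers alone.

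For each class with at least 100 cells in each library, counts were summed and given as CPM of the class total with exact Poisson intervals. Log2 ratios used 0.5 added to each count and had exact conditional binomial intervals. All intervals have a confidence level of 95%. A gene with 0 counts in 1 library and more than 3 in the other is given as a smallest fold from the interval, and no fold was given where both were at or under 3. Class shares had Clopper-Pearson intervals. No replicates were present, so no test between groups was run.

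Cell type markers, 24 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. A list member was measured if it had at least 20 counts in the class over both libraries, and a list needed 3 measured members. List medians had intervals from 1000 Poisson resamples. Each list was placed among 10000 random lists of the same size, matched on expression in 20 bins, as a description of these libraries. Members past 1.5-fold were counted as higher or lower.

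The named genes of a class were the 6 highest and 6 lowest ratios, the 4 members of each list with the largest ratios and a fixed set of cytokine, adhesion, keratin and sex-linked genes. The highest and lowest were taken among genes with a mean CPM of at least 50, at least 50 counts and a class CPM of at least 50% of the library CPM. Mitochondrial, ribosomal protein, haemoglobin and unnamed gene models were left out there. Shares of cells with a count of 12 genes were computed after thinning each cell to 500 counts, with a class that should lack the gene as the control where there was one.

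No cluster was named neutrophil or dendritic cell, so the neutrophil effector list and the other lists for those classes were not run. Langerhans cell-like cells were left out of the gene comparison because 1 library held fewer than 100, and the levels of a few of their genes are given only as an observation. The hair matrix class is not part of the keratinocyte class as defined, and its gene levels were used only to check its name.

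The alternatives were at most 10% mitochondrial counts, at least 500 genes, at most 5000 genes, doublets kept, resolutions 0.5 and 2, and 20 components. Others were scaling by TMM or DESeq2 factors, totals without mitochondrial and ribosomal protein genes, means over cells and 5% of the all-cell profile subtracted. List alternatives were members with at least 50 counts and 1 CPM added, and shares were also thinned to 1000 counts or not thinned. After the data were seen, 4 more were added: 1 doublet score limit for both libraries, clustering without the listed genes, unnamed clusters added back and lists over all retained cells.

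The gene comparison was tested on simulated data with 50 genes changed per fold. The simulated counts were Poisson draws from the pooled profile of both libraries in each class. Intervals held the true fold for 95.9% to 96.6% of genes. Such coverage follows from the Poisson draws, so it checks the code only. It does not show how the intervals or percentiles hold for counts that come from few cells. For a true 2-fold change the median estimate was 2.01 in T and NK cell-like, 1.95 in macrophage and monocyte-like, 2.03 in keratinocyte-like, 1.99 in fibroblast-like and 1.99 in blood endothelial-like cells. For a true fold of 0.5 it was 0.528, 0.517, 0.494, 0.515 and 0.542 in the same order. Of the genes changed to a fold of 0.5, 80%, 88%, 94%, 90% and 84% passed 1.5-fold. Unchanged genes passed 1.5-fold from counting error alone in 19.9%, 11.3%, 6.61%, 6.73% and 16.2% of cases in the same order. Unchanged lists lay at percentiles from 16.9 to 84.3, and doubled lists at 100.

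Tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9. R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 gave the scaling factors only.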

Results

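Single-cell RNA profiles were collected from the dorsal skin of C57BL/6 mice aged 7 weeks. One library came from skin treated with imiquimod, a Toll-like receptor 7 agonist that causes psoriasis-like inflammation in mouse skin. The other came from skin given imiquimod together with Shi-Bi-Man, the natural product under study. Each group held 1 library, so no difference had a replicate check and no test between groups was possible. All intervals below are 95% intervals that cover counting error only. Ratios are given as log2 of the value in the Shi-Bi-Man plus imiquimod library over the value in the imiquimod library.

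The imiquimod library held 11316 barcodes and 28920316 counts, with a median of 1617 counts per barcode and a range from 500 to 37288. The Shi-Bi-Man plus imiquimod library held 8054 barcodes and 20837259 counts, with a median of 1762 and a range from 500 to 27703. After filtering, 11017 and 7863 cells remained. Xist, transcribed from the inactive X chromosome, had 3076 and 3212 counts in the imiquimod and Shi-Bi-Man plus imiquimod libraries, and the Y-linked gene Ddx3y had 11 and 16.

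The series asked how Shi-Bi-Man acts on psoriasis-like skin, with the IL-23/Th17 axis and endothelial activation through CXCL16 named in its title. The first comparison was of the cells recovered. T and NK cell-like cells made up 22.7% of the imiquimod library (21.97 to 23.5) and 6.47% of the Shi-Bi-Man plus imiquimod library (5.94 to 7.04), a log2 ratio of -1.81 (-1.94 to -1.68). Langerhans cell-like cells made up 5.46% and 0.865%, a log2 ratio of -2.66. Keratinocyte-like cells went the other way, at 11.7% (11.1 to 12.3) and 29.8% (28.8 to 30.8), a log2 ratio of 1.35 (1.26 to 1.44). Immune classes together made up 43.0% of cells in the imiquimod library and 17.2% in the other, a log2 ratio of -1.32.

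Among the immune classes, macrophage and monocyte-like cells made up 14.1% and 9.67% of all retained cells, a log2 ratio of -0.55 (-0.67 to -0.43). Of immune cells alone, however, their share was 32.9% with imiquimod and 56.0% with Shi-Bi-Man plus imiquimod, so the direction turned (0.77). The T and NK cell-like share of immune cells was 52.9% and 37.5% (-0.50), and that of Langerhans cell-like cells 12.7% and 5.01% (-1.34). Mast cell-like cells numbered 68 and 19, or 0.617% and 0.242% (-1.35). Blood endothelial-like cells made up 4.54% (4.16 to 4.94) and 3.17% (2.79 to 3.58), a log2 ratio of -0.52 (-0.73 to -0.30). Sebaceous gland-like cells made up 6.45% and 3.24% (-0.99), and fibroblast-like cells 14.1% and 23.6% (0.74). Pericyte and smooth muscle-like cells made up 2.04% and 2.37%, a ratio whose interval spanned 0 (0.21, -0.07 to 0.49). Lymphatic endothelial-like cells made up 1.40% and 2.06% (0.56), melanocyte-like cells 0.590% and 0.916%, and Schwann and glia-like cells 0.663% and 0.471%. Hair matrix and shaft-like cells numbered 138 and 261. The 138 cells with imiquimod, however, had 0 counts of Krt71, Krt25 and Krt28, against 542, 482 and 446 in the other library. Cst6, an upper hair follicle marker, stood at 3588 and 349 CPM in this class. The cells under this name were therefore not shown to be of the same type in both libraries.

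Clusters 4, 7 and 13 stayed outside the named classes. The first, led by S100a8, S100a9, Krt6b and Krt16, made up 7.27% and 2.80% of cells, and the next, led by Coch, Lrrc15 and Fmod, 4.61% and 5.28%. The last, led by Inhba, Sox18 and Rspo3, made up 2.41% and 5.74%. With cluster 4 added, the keratinocyte-like shares were 19.0% and 32.6%, which brought the log2 ratio down to 0.78. With cluster 7 added, the fibroblast-like shares were 18.7% and 28.9% (0.62). When the cells were clustered without the genes of the fixed lists, the T and NK cell-like log2 ratio was -1.82 and the keratinocyte-like one 0.78.

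**Figure D1:**
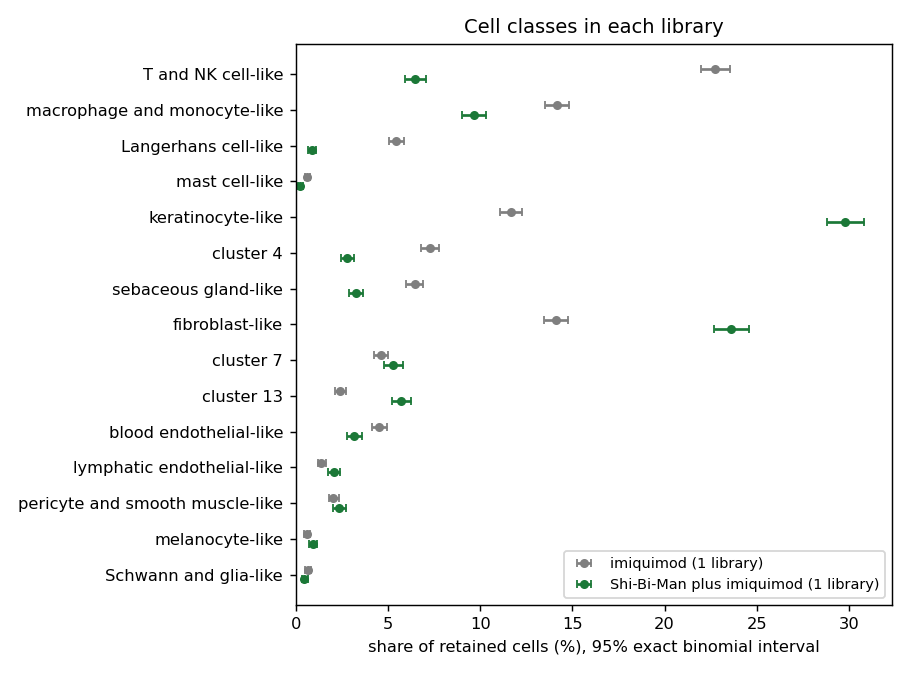
Share of retained cells (%, x axis) in each cell class or unnamed cluster (y axis), with points for the imiquimod library (grey) and the Shi-Bi-Man plus imiquimod library (green) and bars for 95% exact binomial intervals. T and NK cell-like cells stood at 22.7% and 6.47%, keratinocyte-like cells at 11.7% and 29.8%.

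The T and NK cell-like class was compared next, since Th17 cytokines are made there. The transcripts of IL-17A, IL-17F and IL-22, the cytokines that drive epidermal inflammation in psoriasis, were lower in the Shi-Bi-Man plus imiquimod library, while transcripts of cytotoxic and type 1 effector genes were higher. Il17a stood at 5399 CPM (counts scaled to a class total of 1e6) with imiquimod and 1629 CPM with Shi-Bi-Man plus imiquimod, a log2 ratio of -1.73 (-1.83 to -1.63). The same ratio was -1.49 (-1.62 to -1.36) for Il17f, at 3052 and 1088 CPM, and -2.59 (-3.21 to -2.07) for Il22, at 352 and 57.7 CPM. Different clusters held most of the class in the libraries: cluster 0, led by Il17a, Il17f and Trdc, held 68.6% of its 2506 cells with imiquimod and 35.2% of its 509 cells with Shi-Bi-Man plus imiquimod. Cluster 9, led by Ccl5, Gzmc and Nkg7, held 26.5% and 41.3%, and cluster 22, led by Cd7, Trat1 and Xcl1, 4.87% and 23.6%.

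Of 24 measured genes of IL-17-producing T cells, 0 were at least 1.5-fold higher, 13 at least 1.5-fold lower and 11 in between. Their median log2 ratio was -0.73 (-0.93 to -0.61), at percentile 0 of 10000 random lists matched on expression. Cd163l1, a scavenger receptor gene of γδ T cells, stood at -1.40, and Il23r, the receptor through which IL-23 acts on these cells, at -0.35 (-0.77 to 0.03), a difference not detectable at this depth. Within clusters 0, 9 and 22 the median of the list was -0.33, -0.16 and -0.37. Il17a is ENSMUSG00000025929, on chromosome 1 from 20730905 to 20734496, and Il17f is ENSMUSG00000041872, on chromosome 1 from 20777146 to 20790617. Il22 is ENSMUSG00000074695, on chromosome 10 from 118204942 to 118210047, all in GRCm38.

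Each cell was also thinned to 500 counts, which left out no T and NK cell-like cell. A count of Il17a was then found in 52.0% of these cells with imiquimod (50.02 to 54.0) and 18.9% with Shi-Bi-Man plus imiquimod (15.6 to 22.5). Without thinning the shares were 59.0% and 22.2%, at median depths of 1006 and 780 counts. Fibroblast-like cells, which should lack Il17a, had it in 2.83% and 0.162% after thinning and in 7.65% and 0.593% before, at median depths of 2161.5 and 2097. Il17f was found in 37.2% and 12.6% of T and NK cell-like cells after thinning (46.9% and 14.5% before), against 1.22% and 0.108% of fibroblast-like cells. Il22 was found in 4.99% and 1.77% (6.66% and 2.55% before), against 0.257% and 0 of 1856 fibroblast-like cells, which allows a share of up to 0.199%.

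Cytotoxic and type 1 genes showed the opposite direction across the class, with 13 of 18 measured members higher, 1 lower and 4 in between, and a median of 1.30 (1.17 to 1.66), at percentile 100. Gzma, a granule protease gene, stood at 71.9 and 847 CPM (3.56), and the chemokine genes Ccl4, Ccl5 and Ccl3 at 3.13, 2.79 and 2.23. Within clusters 0, 9 and 22 the median of this list was 0.24, 0.10 and 0.44. Of 13 regulatory T cell genes, 6 were higher and 0 lower, with a median of 0.58 (percentile 99.9), including Foxp3, the lineage transcription factor, at 16.7 and 49.4 CPM (1.58), Klrg1 (1.91) and Tnfrsf4 (1.33). Activation genes had 6 of 15 members higher and 2 lower (median 0.16, percentile 91.5), with Tnf at 1.03 and the checkpoint receptor gene Pdcd1 at -0.91. Interferon response genes had 5 of 14 higher and 0 lower (0.33), with Isg15 at 1.11. Rtp4, with 18 and 8 counts, stood at 1.53 (0.07 to 2.75) but turned to -0.13 with at least 500 genes per cell. Proliferation genes had 1 of 30 higher and 19 lower, with a median of -0.66 (percentile 0), and among them were Birc5 (-2.24), Nusap1 (-2.07) and Mki67 (-0.94). The medians of the cytotoxic, regulatory, activation and proliferation lists turned to -0.83, -1.01, -0.88 and 0.17 over all retained cells, where class shares also enter.

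The genes with the largest ratios in this class outside the lists were Il5, a type 2 cytokine gene, at 8.21 and 111 CPM (3.75), Avil (2.71) and Il12rb2 (2.65). Immunoglobulin genes Iglc3, Jchain and Ighm were among the lowest, but 94.2% of the Iglc3 counts of the imiquimod library came from 1 cell. Scaling by TMM or DESeq2 factors lowered every log2 ratio of this class by 0.14 or 0.13, which turned none of the directions of the class as a whole given above, and the values within clusters were not rescaled.

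CXCR6, the receptor of CXCL16, is carried by tissue T cells. Cxcr6 stood at 1384 and 700 CPM in T and NK cell-like cells, a log2 ratio of -0.98 (-1.15 to -0.82). It was found in 41.3% and 22.4% of these cells after thinning (58.9% and 31.6% before), against 1.29% and 0.216% of fibroblast-like cells. At the imiquimod mix of T and NK clusters found without the listed genes, the Cxcr6 ratio was smaller, at -0.62. Among those clusters Cxcr6 stood at -0.59, -0.92 and -0.61, and at 0.10 in the one of 556 and 142 cells. Its ligand gene Cxcl16 was lower in macrophage and monocyte-like cells, at 365 and 147 CPM (-1.31, -1.57 to -1.07), and was found in 10.2% and 4.47% of them after thinning (23.0% and 13.7% before), against 1.16% and 0.7004% of fibroblast-like cells (6.04% and 3.18% before). In keratinocyte-like cells it stood at 130 and 95.4 CPM (-0.45, -0.59 to -0.30). In fibroblast-like cells, at 31.7 and 15.8 CPM, and blood endothelial-like cells, at 43.7 and 38.5 CPM, it was not separable from free RNA, since T and NK cell-like cells had 28.2 and 33.0 CPM. The endothelial values rested on 52 and 16 counts (-0.15, -1.09 to 0.65). Over all retained cells, where class shares also enter, the log2 ratio of Cxcl16 was -1.16. Langerhans cell-like cells held 36.2% and 8.59% of all Cxcl16 counts and made up 5.46% and 0.865% of cells. Cxcr6 is ENSMUSG00000048521, on chromosome 9 from 123806475 to 123811760, and Cxcl16 is ENSMUSG00000018920, on chromosome 11 from 70453983 to 70459984.

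The list of Cxcl16, Cxcr6 and the proteases Adam10 and Adam17, which shed CXCL16 from the cell surface, had a median of -0.24 in T and NK cell-like cells (percentile 16.7), with 1 of 4 members, Cxcr6, lower. The list was not read in the other classes. T and NK cell-like cells held 88.5% and 87.6% of all Cxcr6 counts, and Cxcr6 stood at 27.3 and 4.62 CPM in macrophage and monocyte-like cells against 30.1 and 3.89 CPM in fibroblast-like cells. Blood endothelial-like cells had more Cxcr6 than fibroblast-like cells with imiquimod, at 57.95 CPM and 0, and also more Il17a, at 211 CPM and 0 against 117 and 2.92 CPM.

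Macrophage and monocyte-like cells were compared because myeloid cells can make IL-23. Genes of the IL-23 and inflammatory cytokine list differed in both directions there, while interferon response genes leaned higher and proliferation genes lower with Shi-Bi-Man. Il23a and Il12b, which encode the subunits of IL-23, had 1 count each with imiquimod and 0 each with Shi-Bi-Man plus imiquimod in this class, too few for a comparison. The class came from cluster 1, led by Lyz1, Lyz2 and Mpeg1 (1061 and 463 cells), and cluster 10, led by Cd209f, Ccl8 and F13a1 (497 and 297 cells).

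Of 25 measured genes of the cytokine list, 5 were higher, 5 lower and 15 in between, with a median of 0.13 (0.01 to 0.25, percentile 94.6). The median was 0.16 in cluster 1 and -0.30 in cluster 10. Cxcl9, a chemokine gene induced by interferon-γ, stood at 27.3 and 85.9 CPM (1.65), Ccl22 at 2.25 and Ccl5 at 1.40, while Cxcl3, a neutrophil chemokine gene, had 33 counts and 1 (-3.196, -9.11 to -1.18). Il1b stood at 514 and 389 CPM (-0.40, -0.56 to -0.24) and was found in 14.7% and 8.82% of cells after thinning (27.4% and 15.5% before), against 0.386% and 0.216% of fibroblast-like cells. Tnf showed no detectable difference (-0.15, -0.55 to 0.22). Il6 was not separable from free RNA in macrophage and monocyte-like cells (48.9 and 48.9 CPM) or keratinocyte-like cells (28.0 and 93.4 CPM), since T and NK cell-like cells had 35.5 and 88.6 CPM. Of the 144 and 75 Il23a counts of the libraries, keratinocyte-like cells held 44 and 54 (-0.51, -1.11 to 0.10), and with cluster 4 added 113 and 57 (-0.99, -1.48 to -0.52).

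Interferon response genes had 10 of 27 members higher and 1 lower in macrophage and monocyte-like cells, with a median of 0.45 (percentile 99.98). Gbp2, a guanylate-binding protein gene, stood at 59.5 and 209 CPM (1.81), and Mx1, an antiviral gene, at 1.53. Tissue-resident and repair genes had 7 of 22 higher and 2 lower, with a median of 0.24 also when the member at 0 was set to its bound (percentile 100), and medians of 0.69 in cluster 1 and -0.04 in cluster 10. Ccl8, a chemokine gene of dermal macrophages, stood at 1837 and 8136 CPM (2.15), Trem2 at 0.94 and Chil3 at -1.96, and Arg1, with 20 counts and 0, was at least 2.74-fold lower. MHC class II genes had 1 of 13 higher and 2 lower (median 0.21, percentile 97.7), with the class II transactivator gene Ciita at 0.67 and the costimulatory gene Cd80 at -1.12. Proliferation genes had 0 of 30 higher and 15 lower, with a median of -0.67 (percentile 0), including Stmn1 (-1.48) and Mki67 (-1.31). The medians of the repair, class II and proliferation lists turned to -0.35, -1.58 and 0.17 over all retained cells. Outside the lists, Iigp1 stood at 1.67, Cd72 at -3.22 and Cxcl13, a B cell chemokine gene, at -2.38.

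Keratinocyte-like cells were compared to see how the epidermal response to IL-17 differed. Cornification genes were much higher in the Shi-Bi-Man plus imiquimod library. The antimicrobial and stress genes S100a8, S100a9, Lcn2 and Krt6a, which mark the psoriatic epidermis, were lower. S100a8 stood at 380 and 9.31 CPM, a log2 ratio of -5.34 (-5.69 to -5.03), S100a9 at 165 and 12.1 CPM (-3.76), Lcn2 at 142 and 5.38 CPM (-4.71) and Krt6a at 652 and 177 CPM (-1.88). The Shi-Bi-Man levels of S100a8 and Lcn2 were near free RNA, since T and NK cell-like cells had 119 and 8.24 CPM and 34.1 and 4.12 CPM. Krt16, a keratin gene of hyperproliferative epidermis, showed no detectable difference in this class (-0.04, -0.13 to 0.04) and was on the other side of 0 under TMM scaling (0.08), but with cluster 4 added it stood at -1.72. Most of the class lay in cluster 2 (636 cells), led by Lhx2, Ptn and Cxcl14, and cluster 15 (514 cells), led by Cst6, Defb6 and Krt79, with imiquimod. With Shi-Bi-Man plus imiquimod it lay in cluster 8 (865 cells), cluster 2 (668 cells) and cluster 16 (454 cells), led by Lsmem1, Tango6 and Serpinb10. Cluster 8, led by Mt4, Krt10 and Krt77, held 30 cells with imiquimod, and cluster 21, led by Lor and Flg, held 5 and 239 cells. Levels of the class as a whole therefore also follow this mix of clusters.

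The list of psoriatic and IL-17/IL-36 response genes had no single direction across the class as named. S100a8 and S100a9 belong to this list, led cluster 4 and were also neutrophil markers in the naming rule. Leaving cluster 4 out of the class was thus not independent of the list. With imiquimod, cluster 4 held 20665 of the 22609 S100a8 counts of keratinocyte-like cells and cluster 4 together. Across the class 14 of 36 measured members were higher, 10 lower and 12 in between, with a median of 0.47 (0.23 to 0.51, percentile 100) and a mean of -0.09. With cluster 4 added the median turned to -0.52, with 5 of 37 higher and 18 lower (percentile 0), and when cells were clustered without the listed genes it was -0.57, and over all retained cells -0.44. Within single clusters the median was lower in each of the 4 that held at least 100 cells per library, at -0.80 in cluster 2, -1.76 in cluster 4, -0.55 in cluster 15 and -0.47 in cluster 16. With members at 0 set to their bound, the medians of clusters 4 and 15 were -1.44 and -0.50. The cells of cluster 4 differed in marker genes between the libraries. The upper hair follicle marker Krt79 stood at 2425 and 60.3 CPM there, and the basal marker Krt15 at 516 and 6596 CPM. Medians within cluster 4, for this and other lists, can therefore also follow a different mix of cells. The members with the largest ratios were S100a8, Il19 (-4.78), Lcn2 and, in the other direction, Sprr2h, a cornified envelope gene, at 76.6 and 1159 CPM (3.92). With cluster 4 added, S100a8 stood at 2382 and 21.8 CPM (-6.77), S100a9 at -5.98, Krt6a at -2.77 and Lcn2 at -4.28.

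Differentiation and barrier genes had 29 of 30 measured members higher and 1 lower, with a median of 2.24 (2.05 to 2.31, percentile 100), also with the 5 members at 0 set to their bound. The late cornified envelope genes Lce1a1, Lce1b, Lce1c and Lce1m had 0 counts with imiquimod and were at least 47.8-fold, 45.7-fold, 43.0-fold and 41.1-fold higher. Lor, which encodes the main cornified envelope protein, stood at 9.97 and 278 CPM (4.79). The median was 1.55 with cluster 4 added and 1.54 when cells were clustered without the listed genes. Within clusters 2 and 16 it was 0.99 and 0.96, in cluster 15 0.18, and in cluster 4 -1.19. After the fibroblast CPM was subtracted, the medians of clusters 2 and 16 were -0.05 and 1.10. In cluster 2, however, only 7 of 15 members were above the fibroblast CPM in both libraries. Free RNA of this kind differed between the libraries: Krt10, chosen after its values were seen, was found before thinning in 24.0% of T and NK cell-like cells with imiquimod and 64.2% with Shi-Bi-Man plus imiquimod.

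Proliferation genes had 0 of 30 members past 1.5-fold in either direction across keratinocyte-like cells and a median of 0.10 (percentile 96.7), and Mki67 stood at 0.03 (-0.11 to 0.17). With cluster 4 added, 7 of 30 were higher and 0 lower (median 0.42, percentile 100), and Mki67 stood at 0.34. In cluster 2 alone, however, 30 of 30 were higher (median 1.30), and in cluster 4 alone 25 of 30 (1.76). Values of this list within clusters 15 and 16 are not given, so no direction shared by all of these clusters can be read. Hair follicle genes had 5 of 24 higher and 6 lower (median -0.13, percentile 36.1), with the follicle stem cell gene Sox9 at -1.79, the BMP and WNT antagonist gene Sostdc1 at -1.87, Fst at -2.33 and Shh, with 1 count and 43, at 4.06 (2.07 to 9.96). Interferon response genes had 2 of 20 higher and 3 lower (0.01). Skint5, an epidermal gene of the differentiation list, stood at 5.18. Outside the lists, the highest ratios were those of Sprr2i (5.67), the metallothionein gene Mt4 (4.97), Skint11 (4.67) and Sprr2f (4.49). The lowest included Gpx2 (-4.33), Klk6 (-4.10) and Chil1, a chitinase-like gene, at 506 and 30.2 CPM (-4.07). Scaling by TMM or DESeq2 factors added 0.12 or 0.11 to every log2 ratio of this class.

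**Figure D2:**
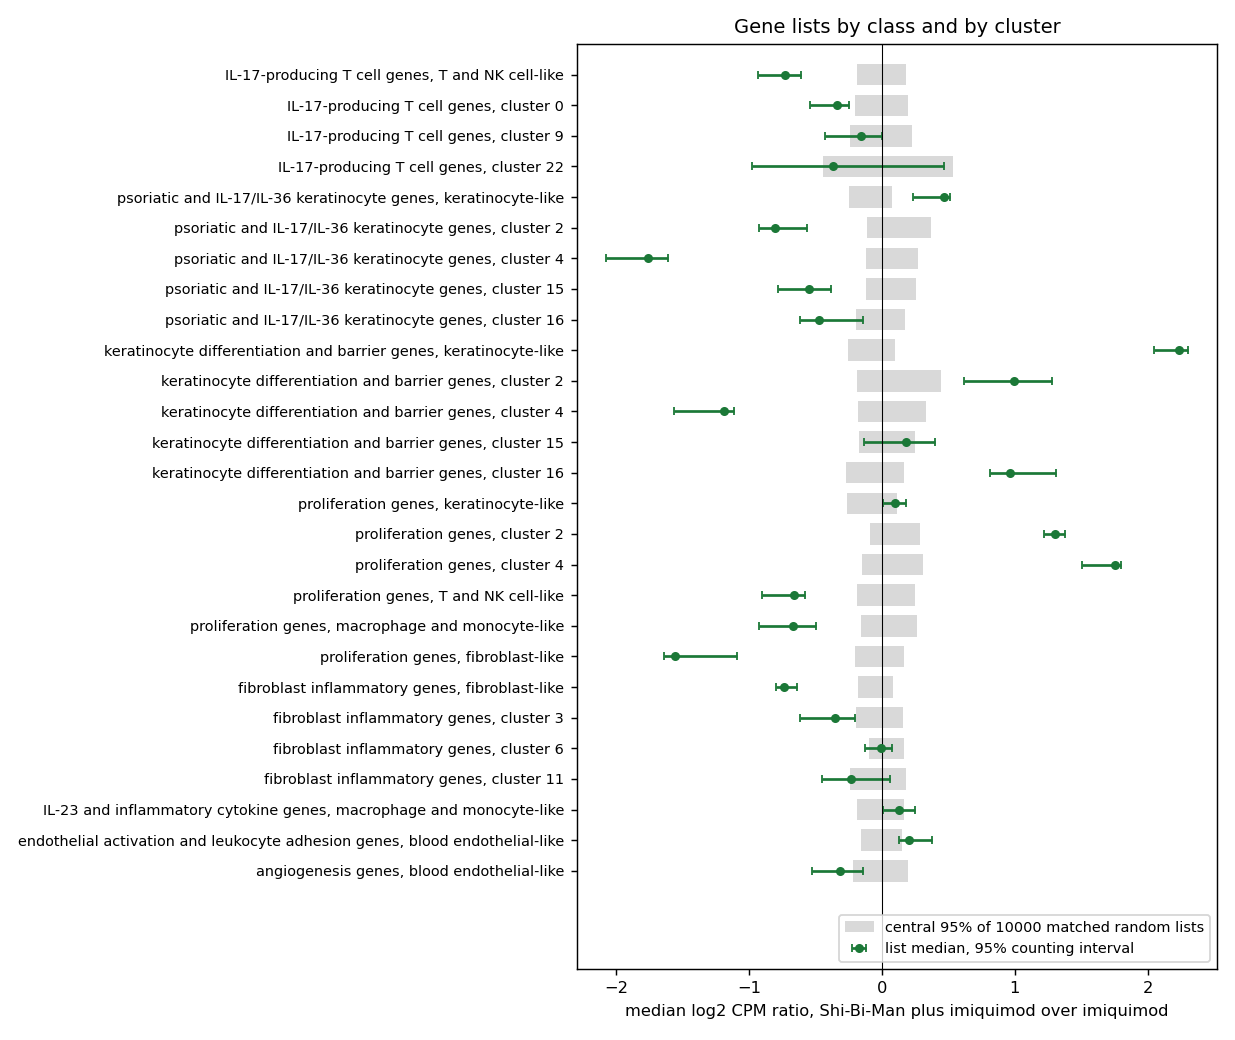
Median log2 CPM ratio of each gene list (x axis, Shi-Bi-Man plus imiquimod over imiquimod) by cell class or cluster (y axis), with green points and bars for medians and 95% counting intervals and grey bars for the central 95% of 10000 matched random lists. The psoriatic list stood at 0.47 in keratinocyte-like cells but between -1.76 and -0.47 within clusters 2, 4, 15 and 16.

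Fibroblast-like cells can answer IL-17 with chemokines and acute-phase proteins. Inflammatory genes were lower in the Shi-Bi-Man plus imiquimod library, with 0 of 30 measured members higher, 19 lower and 11 in between, and a median of -0.73 (-0.80 to -0.64, percentile 0), unmoved with the member at 0 set to its bound. Saa3, an acute-phase gene, stood at 1146 and 35.7 CPM (-5.00, -5.25 to -4.77), and the neutrophil chemokine gene Cxcl5 at -1.95. Lcn2, at 65.8 and 1.94 CPM, was not separable from free RNA with Shi-Bi-Man plus imiquimod, since T and NK cell-like cells had 34.1 and 4.12 CPM. Saa1, with 27 counts and 0, was at least 9.79-fold lower, and Il6 stood at 830 and 589 CPM (-0.50, -0.57 to -0.42). Saa3 is ENSMUSG00000040026, on chromosome 7 from 46711998 to 46715700.

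The fibroblast-like class also drew on different clusters. Cluster 6, led by Gpx3, Thbs4 and Myoc, held 611 of its 1556 cells with imiquimod and 327 of 1856 with Shi-Bi-Man plus imiquimod. Cluster 3, led by Saa3, Cyp2f2 and Cpxm1, held 454 and 811, and cluster 11, led by Igfbp2, Mme and Sema3a, 183 and 575. Within clusters 3, 6 and 11 the median of the inflammatory list was -0.35, 0.00 and -0.23, smaller than in the class. Cluster 19, with 245 and 112 cells, also reached the minimum size, but its median is not given.

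Matrix genes had 3 of 29 members higher and 6 lower, with a median of -0.16 (percentile 8.37). Col1a1, a chain of the main dermal collagen, stood at 10791 and 24706 CPM (1.20, 1.18 to 1.21), while Tnc, a matrix gene of wounds and inflamed skin, stood at 599 and 87.9 CPM (-2.77), Postn at -1.54 and Col12a1 at -1.17. Proliferation genes had 0 of 29 higher and 23 lower, with a median of -1.55 (percentile 0) and Top2a at -2.26 and Mki67 at -2.08. With cluster 7 added, that median turned to 0.30, and over all retained cells to 0.17. Interferon response genes had 2 of 25 higher and 4 lower (0.07), with medians of 0.06, 0.63 and 1.08 in clusters 3, 6 and 11. Outside the lists, the lowest ratios were those of Coch (-3.02), Prg4 (-2.64), the metalloproteinase gene Mmp11 (-2.57) and Thbs4 (-2.19). The highest were those of Igfbp2, an IGF-binding protein gene, at 60.5 and 670 CPM (3.47), Car3 (2.35), Ppp1r14a (2.05), Cyp2f2 (2.005), Aldh3a1 (1.94) and Cdh4 (1.86).

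Blood endothelial-like cells were compared for the activation named in the series title. The selectin genes Sele and Selp, whose products slow leukocytes on activated venules, were not lower with Shi-Bi-Man across the class, and the adhesion genes Icam1 and Vcam1 showed no detectable difference. Selp stood at 2463 and 4495 CPM, a log2 ratio of 0.87 (0.78 to 0.95), and Sele at 1664 and 2053 CPM (0.30, 0.19 to 0.42). Icam1 stood at 1067 and 983 CPM (-0.12, -0.28 to 0.04) and Vcam1 at 374 and 385 CPM (0.04, -0.23 to 0.31), which turned to -0.28 when cells were weighted equally. The class was 1 cluster with 500 and 249 cells, at median depths of 1853 and 1252 counts. At resolution 2 it split, with 247 and 172 cells in 1 cluster (Sele -0.20, Selp 0.33) and 254 and 76 in the other (Sele -1.29, Selp -1.86). Weighted by the imiquimod mix of these clusters, Sele turned to -0.27 and Selp stood at 0.27. Over all retained cells, where the share of endothelial cells also enters, Sele stood at -0.74 and Selp at -0.14.

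After thinning, a Selp count was found in 41.6% and 58.6% of these cells (51.6% and 63.9% before), against 0.771% and 0.485% of fibroblast-like cells. Sele was found in 34.0% and 41.4% (47.0% and 55.8% before), against 0.450% and 0.108%. Icam1 was found in 33.2% and 34.1% (67.0% and 61.4% before, the other direction), and no class lacked it, with sebaceous gland-like cells lowest among the compared classes at 1.97% and 3.53% (14.9% and 16.9% before). Vcam1 was found in 10.8% and 10.8% (21.4% and 25.7% before), against 0.239% and 0.393% of T and NK cell-like cells. Cxcl16 was found in 1.40% and 2.41% (8.20% and 4.42% before, the other direction), against 1.36% and 0.786% of T and NK cell-like cells (3.19% and 2.55% before), near the level of free RNA. Sele is ENSMUSG00000026582, on chromosome 1 from 164048234 to 164057677, and Selp is ENSMUSG00000026580, on chromosome 1 from 164115264 to 164150026. Icam1 is ENSMUSG00000037405, on chromosome 9 from 21015985 to 21028817, and Vcam1 is ENSMUSG00000027962, on chromosome 3 from 116109949 to 116129688.

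**Figure D3:**
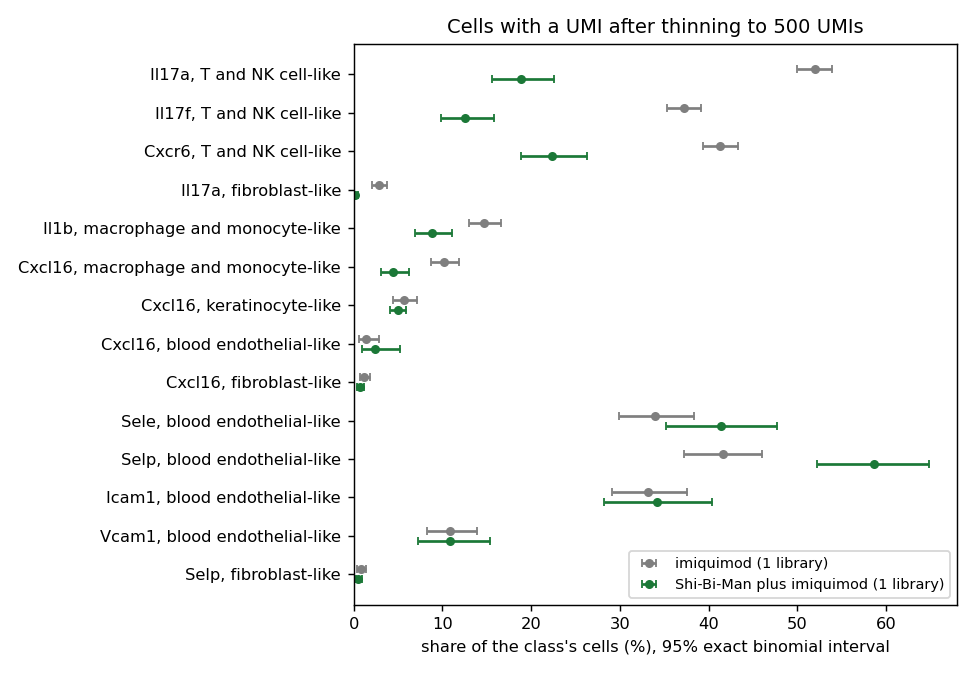
Share of the cells of a class with at least 1 count of a gene after thinning each cell to 500 counts (%, x axis) by gene and class (y axis), for the imiquimod library (grey) and the Shi-Bi-Man plus imiquimod library (green), with 95% exact binomial intervals. Il17a was found in 52.0% and 18.9% of T and NK cell-like cells, and Selp in 41.6% and 58.6% of blood endothelial-like cells.

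Of 30 measured endothelial activation and leukocyte adhesion genes, 10 were higher, 4 lower and 16 in between, with a median of 0.20 (0.13 to 0.38, percentile 99.4). The members with the largest ratios went both ways. Cxcl9 stood at 102 and 317 CPM (1.64), whereas the monocyte chemokine gene Ccl2 stood at 604 and 190 CPM (-1.66, -2.02 to -1.33), Cxcl2 at -1.35 and the IL-17 receptor gene Il17ra, with 27 counts and 2, at -1.94 (-5.36 to -0.25). Il6 stood at 2236 and 2944 CPM (0.40) and Socs3, a feedback inhibitor of cytokine signalling, at 1.13. Over all retained cells the median of the list turned to -0.21.

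Angiogenesis genes had 1 of 25 members higher and 9 lower, with a median of -0.32 (-0.52 to -0.14, percentile 0.18), including Pgf (-1.50), Cxcr4 (-1.42) and Notch4 (-1.19). Junction genes had 0 of 11 past 1.5-fold in either direction (median 0.13, percentile 84.8), with Jam2 at 0.48 and S1pr1, a receptor that stabilises the vessel barrier, at -0.37. Interferon response genes had 10 of 25 higher and 2 lower, with a median of 0.50 (percentile 100), and Ifit1 stood at 160 and 529 CPM (1.73) and Ifit3 at 1.33. Proliferation genes had 2 of 20 higher and 10 lower (median -0.47, percentile 0.56), with a median of 0.17 over all retained cells. Outside the lists, the immune checkpoint ligand gene Cd274 stood at 1.87, Slfn4 at 2.19 and Camk1d at 2.03, while Serpine2 stood at -2.55, Olfml2a at -1.90 and the mural cell marker Rgs5 at -1.72.

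Metabolic and quality lists were compared in every class. Oxidative phosphorylation genes had medians of -0.40 in keratinocyte-like, -0.33 in macrophage and monocyte-like, -0.23 in T and NK cell-like, -0.14 in blood endothelial-like and -0.07 in fibroblast-like cells. Cox8a, a subunit gene of cytochrome c oxidase, stood at 850 and 467 CPM in keratinocyte-like cells (-0.87). Glycolysis and hypoxia genes had a median of -0.36 in macrophage and monocyte-like cells, where 0 of 23 were higher and 5 lower, among them Vegfa (-0.78). In keratinocyte-like, T and NK cell-like, blood endothelial-like and fibroblast-like cells this list stood at 0.12, 0.10, 0.02 and -0.01, and under TMM scaling the signs in T and NK cell-like (-0.04) and fibroblast-like cells (0.01) turned. Dissociation and immediate early genes stood at 0.20 in T and NK cell-like, 0.14 in macrophage and monocyte-like, 0.07 in blood endothelial-like, 0.06 in fibroblast-like and -0.06 in keratinocyte-like cells, with the heat shock gene Hspa1b at 1.46, 1.57, 0.50, 0.45 and 0.96. Ribosomal protein genes stood at 0.07, -0.09, -0.02, -0.24 and -0.24 in the same order, and mitochondrial transcripts at 0.09, -0.13, 0.06, 0.02 and -0.07. Under TMM scaling the signs turned for ribosomal (-0.07) and mitochondrial (-0.05) genes in T and NK cell-like cells and for dissociation (0.07) and mitochondrial (0.05) genes in keratinocyte-like cells. With cells weighted equally, the dissociation (-0.05), ribosomal (0.02) and glycolysis (-0.01) lists turned in blood endothelial-like cells.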

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

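The tests in this part were written after the results were seen, except the share of fibroblast RNA in cluster 2 and the mix of endothelial clusters. No biological explanation was tested, because each group holds 1 library.

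Haemoglobin transcripts appeared in barcodes that the gene minimum left out, a signal in data the comparisons did not use. They made up 364764 of 397358 counts (91.8%) in the imiquimod library and 8028 of 9987 (80.4%) in the Shi-Bi-Man plus imiquimod library.

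Langerhans cell-like cells, too few for the gene comparison, carried cytokine transcripts. The 601 and 68 cells had 1542 and 118 counts of Cxcl16, which were 36.2% and 8.59% of all Cxcl16 counts of the libraries. Il12b had 76 and 18 counts, which were 97.4% and 100% of all Il12b counts. Il1b had 761 and 13 counts (30.3% and 2.39%), and Tnf 139 and 35 (16.9% and 10.9%). These counts follow the number of cells. As CPM of the class total, Cxcl16 stood at 843 and 865 (log2 ratio 0.04, -0.25 to 0.31). Il12b stood at 41.6 and 132 CPM (1.70, 0.84 to 2.42) and Tnf at 76.0 and 257 CPM (1.77, 1.18 to 2.30). Il1b stood at 416 and 95.3 CPM (-2.07, -3.04 to -1.34). With 68 cells in 1 library these levels fall short of the minimum set for a comparison.

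The lower Il17a, Il17f and Il22 levels in T and NK cell-like cells were weighed first. Il17a stood at 117 and 2.92 CPM in fibroblast-like cells, against 5399 and 1629 CPM in T and NK cell-like cells. Free RNA at the fibroblast level was thus a small part of Il17a. The median log2 ratio of -1.699 after that level was subtracted was fixed by levels already seen and is no separate check. CPM levels are already scaled to the class total, so lower depth was checked only on shares of cells with Il17a. With each cell thinned to the same depth, the log2 ratio of these shares was -1.463. Lower depth was thus not the whole cause of the lower share. These shares had already been seen and are no separate check of the levels. At the higher thinning depth, which left out shallower cells, the ratio of shares was -0.9233. At the imiquimod mix of clusters found without the listed genes the median was -1.344, which excludes that mix as the whole cause, although Il17a in those clusters ranged from -3.99 to -0.07. Finer mixes, the treatment and a difference between the skin pieces remain open.

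The higher differentiation and barrier genes of keratinocyte-like cells were weighed next. In cluster 2 the fibroblast CPM was 74.02% of the cluster CPM, so free RNA of cornified cells cannot be told apart from expression there. The median within cluster 2 after subtraction was -0.04877, but only 7 of 15 members were above the fibroblast CPM in both libraries. Cluster 8, led by Mt4, Krt10 and Krt77, held 30 and 865 cells, and cluster 21, led by Lor and Flg, 5 and 239. Fewer cells of these suprabasal-type clusters were thus recovered with imiquimod, but whether this was the whole cause was not decided. In cluster 16, where 23 of 24 members were above the fibroblast CPM, the median was 1.104 after subtraction. That value excludes free RNA at the fibroblast level as the whole cause there. Free RNA differed by class, however. With Shi-Bi-Man plus imiquimod, Krt10 stood at 736 CPM in fibroblast-like and 1613 CPM in T and NK cell-like cells. The higher level was not subtracted, so free RNA beyond the fibroblast level was not excluded. How many cells of each layer were lost in dissociation was not measured.

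Sele and Selp, which were not lower in blood endothelial-like cells, were weighed last. At the imiquimod mix of finer clusters Selp stood at 0.2727, so the mix as a cover for a 1.5-fold lower level was excluded, but Sele stood at -0.27 there. Selp stood at 12.2 and 11.2 CPM in fibroblast-like cells, against 2463 and 4495 CPM in blood endothelial-like cells. Free RNA at the fibroblast level was thus a small part of Selp. The ratio of 0.8713 after that level was subtracted was fixed by these values and is no separate check. One finer cluster of 254 and 76 cells had lower ratios for both, at -1.29 and -1.86, and the other, of 247 and 172 cells, had -0.20 and 0.33.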

How the results depend on the processing

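The settings with 1 doublet limit, clusters without listed genes, unnamed clusters added back and all retained cells were chosen after the data were seen. No paired analysis was possible because each group holds 1 library. Counts of Il23a and Il12b were too few to compare in macrophage and monocyte-like cells. Whether depth or low expression was the reason was not tested. Depth and free RNA limited Cxcl16 in blood endothelial-like cells. Values are log2 ratios. A value moved if it left the 95% counting interval of the reported value. A gene reversed if its ratio was past 1.5-fold with an interval off 0 and its sign turned, so genes nearer 0, such as Krt16 and Vcam1, could change sign without counting as reversed. Sums over all cells also follow class shares, and the share of immune cells has another denominator by construction. For every other value below the cause was not tested.

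With at least 500 genes the shares of T and NK cell-like, macrophage and monocyte-like and keratinocyte-like cells stood at -2.384, -0.6695 and 1.182. Of immune cells, those of T and NK cell-like, macrophage and monocyte-like (reversed) and Langerhans cell-like cells stood at -0.4963, 0.7678 and -1.34. The keratinocyte share was 1.853 at resolution 2, 1.254 with 1 doublet limit, 0.7793 without listed genes and 0.7823 with cluster 4 added back. The fibroblast-like share was 0.6245 with cluster 7 added back.

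Over all retained cells the IL-17 list stood at -2.269, the cytokine list at -0.6539, differentiation at 1.965 and fibroblast inflammatory genes at -0.1367. Reversed there were the cytotoxic (-0.8281), repair (-0.352), psoriatic (-0.4398) and endothelial activation (-0.2123) lists, regulatory T cell genes in T and NK cell-like cells (-1.007) and MHC class II antigen presentation genes in macrophage and monocyte-like cells (-1.579). Proliferation (0.1695) reversed for T and NK cell-like, macrophage and monocyte-like, fibroblast-like and blood endothelial-like cells.

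The psoriatic and IL-17/IL-36 keratinocyte genes in keratinocyte-like cells stood at 0.1694 with at most 10% mitochondrial counts, 0.2065 with at least 500 genes, 0.1669 at resolution 2, 0.07766 with 20 components, 0.5911 under TMM, 0.5797 under DESeq2 scaling and 0.5138 with 5% subtracted. They reversed without listed genes (-0.5717) and with cluster 4 added back (-0.5208). The keratinocyte differentiation and barrier genes in keratinocyte-like cells stood, in the same order of the first 3, at 2.353, 2.377 and 1.858. They were at 2.738 with doublets kept, 2.875 at resolution 0.5, 2.333 with 1 doublet limit, 1.535 without listed genes, 1.554 with cluster 4, 2.357 under TMM, 2.345 under DESeq2 scaling and 2.009 with 1 CPM added.

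The share of T and NK cell-like cells with Il17a was -0.9233 thinned to 1000, which left out 1236 and 362 cells. Reversed genes were Rtp4 in T and NK cell-like cells (-0.1316, at least 500 genes), and in keratinocyte-like cells Cxcr6 (2.532) and Il17a (1.93) with 5% subtracted. With cluster 7 added back, Birc5 in fibroblast-like cells (0.4002), Ccnb1 in fibroblast-like cells (0.2853) and their proliferation list (0.3017) reversed.

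The blood endothelial-like share kept its direction in all 10 settings, from -0.6094 to -0.4671, and the IL-17 list in all 18, from -2.269 to -0.7138. The shares of blood endothelial-like cells with Selp and Sele ranged from 0.3074 to 0.4952 and 0.2482 to 0.4112. Of the other gene values, 5490 stayed within the counting interval and 424 moved outside it. Lists other than the IL-17, cytokine, psoriatic, differentiation, fibroblast inflammatory and endothelial activation lists had 724 values within it. In those lists 118 values moved and 9 reversed. For class shares not named in this part, 53 values stayed and 7 moved.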

Other observations

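The tests named in this part were written after the values were seen, and so were the choices of Krt25 and Krt71. Among the lowest ratios in sebaceous gland-like cells, which make skin lipids, were Lcn2 (-3.47), the phospholipid carrier gene Pctp (-3.23), the fatty alcohol gene Far1 (-2.70) and Elovl7 (-2.44). Among the highest were Paqr7 (2.97), Akr1c18 (2.11), the glucocorticoid target Fkbp5 (1.73) and Serpina3b (1.59).

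Among the highest ratios in pericyte and smooth muscle-like cells were Gbp2 (2.36), Iigp1 (1.91) and Cxcl10 (1.76). The matrix genes Dpt and Eln stood at -3.52 and -2.09 there. In lymphatic endothelial-like cells Cxcl2 stood at -1.81, Serpine2 at -1.48, Sele at 1.29 and the mechanosensor gene Piezo2 at 2.44.

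In cluster 4 Chil1 stood at -7.06, Krt79 at -5.31, Cst6 at -4.64, Krt15 at 3.68 and Mki67 at 1.82. In cluster 7 Saa3 stood at -4.13, Mgp at -3.30, Mcm2 at 2.42 and Mki67 at 1.28. In cluster 13 Igfbp3 stood at -4.47, Aspn at -5.04 and Vcan at 4.56, and Alpl was at least 18.0-fold higher.

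Hair shaft and inner root sheath transcripts differed between the libraries, with 5 and 694 counts of Krt25 and 34 and 1113 of Krt71. The hypothesis was that growing follicles lay in 1 skin piece and not in the other. The 7 measured hair markers had a median of 3.902, which restates the pattern. Keratin-associated protein genes had a median of 1.697, but 3 were measured, with 59 and 69 counts and ratios from -0.80 to 6.15. Growing follicles and uneven capture therefore cannot be told apart.

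Several immunoglobulin transcripts came from few cells. Of the imiquimod library's counts, 94.2% of Iglc3 and 90.5% of Iglc1 came from 1 cell, and 8 and 1 cells held at least 20 counts of Jchain. For Ighm the 10 highest cells held 82.5% of 12518 and 42.9% of 788 counts, and the highest cell 27.4% and 34.1%.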
